A study of Mus musculus with 4 samples.

How the data were processed

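Islet RNA of male C57BL/6 mice aged 10 to 12 weeks was measured in 4 samples, 2 wild type and 2 with a transgene for miR-29a and miR-29b-1 in pancreatic beta cells, grouped by the genotype in the labels. Per the labels' protocols, isolated islets were frozen, RNA was taken with Trizol, and libraries were made from total RNA with an Illumina TruSeq RNA kit. Per the submitters' processing notes, HTSeq 0.6.0 and the genome build GRCm38 were used, and the aligner is not given in the sources used here. The authors deposited 1 table of FPKM with the length of each of 54532 genes. Whether reads were assigned by strand is not given, so reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain.

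FPKM times gene length came to a whole multiple of a single step per library, within 0.001 of a whole number, for 100% of the values above 0, and these multiples were taken as reads. The reads summed to 23730364, 27080907, 23654135 and 21670854 in wild type 1, wild type 2, transgenic 1 and transgenic 2. The step instead corresponds to totals of 23869634, 25927074, 25780368 and 21011933 reads, which are 1.01, 0.957, 1.09 and 0.970 times those sums, so the deposited FPKM hold a further factor per library whose nature is not given. At this depth 1 read of a gene of 1 kilobase is worth 0.0419, 0.0386, 0.0388 and 0.0476 FPKM, and a count of 0 allows up to 3 reads, or 0.126, 0.116, 0.116 and 0.143 FPKM. Exact binomial intervals at 95% are given for shares of reads in a library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Tests that model counts directly were not run, since the table holds FPKM.

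Genes with an FPKM of at least 1 in at least 2 libraries were compared (12716). The test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(FPKM + 1) with genotype as the only term, 2-sided, with Benjamini-Hochberg adjustment over the genes compared and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates those of low genes, unless they are said to be on the reads. The 30 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists. With an estimated correlation camera rests on the few residual degrees of freedom of so few libraries, so it could call hardly any list. The lists are the matrix and other targets of miR-29; beta cell identity and genes silent in beta cells; markers of alpha, of delta, PP and epsilon, acinar, duct, endothelial, stellate and pericyte, macrophage and dendritic, lymphocyte, fat, and Schwann cells and neurons; chemokines and cytokines, NF-kappa-B, interferon response, unfolded protein response, cell cycle, insulin secretion and exocytosis, insulin and growth factor signalling, cholesterol synthesis, glycolysis, oxidative phosphorylation, p53 and apoptosis, immediate early and dissociation stress, growth hormone and prolactin response, mitochondrially encoded, cytosolic ribosomal and exosome genes. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except those the text says were chosen after seeing the data.

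Genes were named by a rule with 4 parts. The first takes, in each direction, the 12 genes with the largest fold change among those past the threshold whose groups do not overlap and whose mean is at least 2 FPKM in the higher group, or, where fewer than 3 pass, the 6 with the smallest p as values only. The second allows up to 4 genes per list with the smallest p, from which the text takes examples. The third always takes the miR-29 genes and their host transcripts, Traf3, the islet hormone genes, Slc16a1, Col1a1, Col3a1, Dnmt3a, Dnmt3b, Mcl1, Onecut2 and Stx1a. The fourth passes over predicted or unnamed models, which removed 1 higher and 22 lower genes. After seeing the data the first part was repeated on the voom fit with library number as a term, where 86 higher and 13 lower genes met it and 3 and 5 predicted models were passed over, and on that fit with the GC curve removed, where 18 and 8 met it and 3 and 4 were passed over. Slc2a2, named for the difference between library numbers, was chosen after its values were seen.

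Because libraries of the same number lay together, fold changes were also computed within each number, and voom in limma was run on the recovered reads with and without the library number as a term. The GC content and length of genes, 3' UTRs and gene types came from GENCODE M21 on GRCm38, matched by gene ID, and 12705 of the 12716 genes had a GC content. In the settings so named, a lowess curve (span 0.3) on GC content was removed from each library. It was fitted to that library's deviations from each gene's mean over all libraries. For the seed test, 3' UTRs of at least 50 bases were searched for the 7 bases pairing with the miR-29 seed, and genes with and without a match were compared by median fold change within 10 bins of UTR length. The same difference was computed for 5760 other 7-base sequences found in 0.67 to 1.5 times as many UTRs. Of the 10874 protein-coding genes 98.5% had such a UTR. Matches of 8 and of 6 bases were alternatives.

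Both kinds of gene test and camera were tested on simulated data before use, with 5 simulations of 12716 genes in which 200 were changed. Reads were drawn from the libraries' own means with a dispersion of 0.00383. With the number difference included, limma without number as a term found 0% of genes changed 1.25-fold, 1.5-fold, 2-fold or 4-fold. Voom with number as a term found 27.2% of genes changed 1.25-fold, 77.2% of those changed 1.5-fold, 92.0% at 2-fold and 95.2% at 4-fold, and called 34 of 62430 unchanged genes. With the GC curve removed it found 30.0%, 73.6%, 92.4% and 95.2%, on reads drawn with a made GC trend in the transgenic libraries. Reads for the other fits held no GC trend between genotypes, unlike the real folds. The 34 false calls and the shares found without GC removal therefore do not carry over to the real folds. Of lists with 30 genes changed 1.4-fold, 5 of 5 were called, and 0 of 45 unchanged lists. These lists were random genes drawn independently, so they lacked the correlation and the shared shift between numbers that real lists can have. The seed test was tested, after its result was seen, on shuffled folds with a made trend on UTR length and a fall laid on 50% of the 1665 genes with a match. Of 20 simulations each, 0 ranked below percentile 2.5 with no fall, 19 with a fall of 0.05 and 20 with one of 0.1. Shuffled folds have no tie to sequence, so these counts do not carry over to the real folds.

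The alternatives were other pseudocounts (0.1 and 0.01), no filter or a filter at 5 FPKM, quantile and trimmed-mean scaling, rescaling without exocrine and hormone genes, eBayes without trend or robust, the replicate number as a block, leaving out each library, genes of at least 200 bases, the GC curve, and voom. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.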

Results

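RNA from pancreatic islets of male C57BL/6 mice aged 10 to 12 weeks was sequenced in 4 libraries. Wild-type islets gave 2 libraries and islets of mice carrying a transgene for miR-29a and miR-29b-1 in pancreatic beta cells gave the other 2. miR-29 is a family of microRNAs, short RNAs that pair with messenger RNAs through their seed and lower their levels or translation. Each library carries a number in its name, wild type 1 and 2 and transgenic 1 and 2, and the labels do not say whether a library came from 1 mouse or a pool, or whether the libraries of a group came from separate mice. The p-values given here therefore measure only the spread between these libraries, which may be technical. Values were FPKM (fragments per kilobase of gene, scaled to library size) for 54532 genes, and the reads behind them could be recovered for 100% of the values above 0. Reads in genes came to 23730364 in wild type 1, 27080907 in wild type 2, 23654135 in transgenic 1 and 21670854 in transgenic 2. Of all genes, 12716 had an FPKM of at least 1 in at least 2 libraries and were compared, 10874 of them protein coding. Positions are on GRCm38.

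The largest difference among the libraries lay between those numbered 1 and those numbered 2, in both genotypes. Marker genes of acinar cells, the exocrine cells around the islets, took 0.921% of the reads in wild type 1 (95% exact binomial interval 0.917 to 0.925), 1.34% in transgenic 1 (1.33 to 1.34), 0.185% in wild type 2 (0.183 to 0.187) and 0.307% in transgenic 2 (0.305 to 0.309). The insulin gene Ins2 took 20.1% of the reads in wild type 1 and 12.8% in transgenic 1, against 26.6% and 25.5% in wild type 2 and transgenic 2. Across the genes compared, Pearson's r of log2(FPKM + 1) was 0.985 between the libraries numbered 1 and 0.989 between those numbered 2. It was 0.950 between the wild-type libraries and 0.950 between the transgenic ones, and genes are not independent replicates in these values. The first principal component, with 77.9% of the variance, separated the numbers, and the second had 13.0%. Because of this split, fold changes of transgenic over wild type are given for each number beside those over all libraries.

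The transgene's own loci were examined first. Mir29b-1 (chromosome 6, 31063023 to 31063093) had 0 reads in every library, and Mir29a (chromosome 6, 31062660 to 31062747) had 3 reads in wild type 2 and 0 in the other libraries. The overlapping transcript Gm27019 (chromosome 6, 31063092 to 31063495) had 1 and 3 reads in wild type 1 and 2 and 0 in both transgenic libraries. At the second miR-29 locus, Mir29c and Mir29b-2 (chromosome 1, 195037547 to 195037634 and 195037040 to 195037120) had 0 reads in every library. Their host transcript A330023F24Rik (chromosome 1, 194976375 to 195037904) lay at 1.62 and 1.44 FPKM in wild type 1 and 2 and at 1.80 and 1.55 in transgenic 1 and 2, a log2 fold change of 0.08 ± 0.16 (standard error, n = 2 per group). A count of 0 allows up to 3 reads, and libraries of long RNA do not record mature microRNAs, so these loci check neither the genotype labels nor the level of miR-29a or miR-29b-1.

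The comparison of transgenic with wild-type islets asks which islet transcripts differ when beta cells carry extra miR-29a and miR-29b-1. Acinar genes were higher in transgenic islets of both numbers, with a median log2 fold change of 0.44 in number 1 and 0.59 in number 2 over the 32 compared, 28 of them higher in both. Immediate early genes, which cells switch on within minutes of stimulation or stress, were higher by about as much, with medians of 0.52 and 0.49 over 16 genes, 15 of them higher in both. Cish, a feedback inhibitor of cytokine signalling that growth hormone and prolactin induce, lay at 1.85 and 0.679 FPKM in wild type 1 and 2 and at 4.42 and 2.26 in transgenic 1 and 2. The mitochondrially encoded genes were lower, with medians of -0.25 and -0.15, but of 0.00 and -0.05 in voom with number as a term once each library's curve on GC content was removed. Islet hormone genes other than Ins2 and the lists of known miR-29 targets differed little. No single gene passed the test across all 4 libraries: limma on log2(FPKM + 1) called 0 genes higher and 0 lower at an adjusted p under 0.05, with 83 genes at an unadjusted p under 0.05, and voom on the recovered reads also called 0, with 32. In data simulated with the difference between numbers, that limma test found 0% of genes changed 4-fold, and without it 93.6%.

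With the library number as a term in the model, chosen after seeing the data, voom on the recovered reads called 204 genes higher and 34 lower in transgenic islets. That model leaves a single residual degree of freedom per gene. Its p-values rest largely on variance shared across genes and on how alike the folds of both numbers are, not on spread within genotypes. Of the 238, 198 of the higher and 25 of the lower were protein coding, 15 were predicted gene models, and in 136 the genotypes still overlapped across numbers. The genes called higher had a median GC content of 58.3% and those called lower 43.7%, against 49.7% of the genes compared. Removing the curve on GC content from each library left 81 higher and 30 lower, of which 65 and 13 were among the 238. In simulated data the fit without GC removal found 77.2% of genes changed 1.5-fold and 92.0% of those changed 2-fold. Those data held no GC trend between genotypes, so they do not show how many of the 238 calls are false. The genes that follow are those with the largest changes in this fit among those whose genotypes did not overlap, followed by those that are among the largest only with the GC curve removed.

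Cish (chromosome 9, 107296026 to 107302784) rose by 0.93 in number 1 and 0.96 in number 2 on the log2(FPKM + 1) scale, and 1.42 ± 0.14 on the reads (voom with number as a term, adjusted p = 3.3e-09, n = 2 per group). Snord59a, a small nucleolar RNA gene, had 0 reads in both wild-type libraries and 5 in each transgenic one (voom adjusted p = 0.0250, and 0.0113 with the GC curve removed). Nutf2-ps1, annotated as protein coding and a near copy of Nutf2 whose reads counting can split, rose by 1.01 and 1.52 (adjusted p = 1.5e-04 in the same voom fit). Srp54a, which also has near copies, rose by 0.12 and 0.97 (voom adjusted p = 0.00128). Cntfr, the receptor for ciliary neurotrophic factor, rose from 10.5 and 12.6 FPKM to 19.9 and 16.5 (voom adjusted p = 8.8e-05), and the transcription factor gene Cebpd from 10.0 and 5.65 to 12.5 and 10.9 (5.2e-04). Tysnd1, a peroxisomal protease gene, rose from 9.77 and 9.18 FPKM to 14.3 and 13.9 (voom adjusted p = 8.7e-04), but the call ended once the GC curve was removed, with the fold on the reads going from 0.57 ± 0.11 to 0.29 ± 0.10 (adjusted p = 0.234). The calls of Cebpa, Tmem191c, Fbxo17, C1qtnf12 and Phldb1 also ended there, as their folds went from between 0.55 and 0.79 to between 0.34 and 0.53 (voom adjusted p of 0.25 to 0.428). Of the genes that fell, Cd9, a tetraspanin of the plasma membrane and of vesicles, had the most even values, 9.10 and 8.85 FPKM in wild type against 6.68 and 6.47 in transgenic islets (log2 fold change -0.45 ± 0.12 on the reads, voom adjusted p = 0.0406, and -0.40 ± 0.12, 0.0737, with the GC curve removed). Rbm12b2, Slc2a13, Sult1d1, Zfp35, Malat1 and Zeb1 also fell, by log2 fold changes of -0.52 to -0.42. With the GC curve removed none of these calls held (voom adjusted p of 0.0604 to 0.332), while the fold of Sult1d1 went from -0.44 ± 0.09 to -0.23 ± 0.09 and those of the other 5 to between -0.39 and -0.32. Rpl9-ps6 fell by 0.41 ± 0.10 (voom adjusted p = 0.0257, and 0.0317 with the curve removed), and its reads may be shared with Rpl9. With the GC curve removed, the largest rises also held Otoa (0.56 ± 0.12 on the reads, voom adjusted p = 0.00187), Acbd6 (0.47 ± 0.10, 0.00130), the heat shock protein gene Hspa2 (0.42 ± 0.11, 0.0228), the chondroitin sulfotransferase gene Chst12 (0.40 ± 0.10, 0.0192) and Nfkbia (0.36 ± 0.09, 0.00731), each also called without that step. Socs2 was among these rises as well (0.39 ± 0.10, voom adjusted p = 0.0218) but was not called without that step (0.34 ± 0.11, 0.0804). The largest falls also held Dusp26 (-0.43 ± 0.11, voom adjusted p = 0.0199), Rps6 (-0.34 ± 0.09, 0.0153) and Rpl26 (-0.31 ± 0.09, 0.0340), none of them called without it (-0.24 ± 0.12, -0.15 ± 0.09 and -0.16 ± 0.09; adjusted p = 0.295, 0.426 and 0.353).

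In the test across all 4 libraries, 1 higher and 22 lower predicted gene models were passed over to reach the named genes with the smallest p-values. The genes left were mostly short RNA genes with few reads. Higher in transgenic islets were Snord59a (0 and 0 reads in wild type, 5 and 5 in transgenic islets), Mir7052 (4 and 6 against 13 and 10), Mir6940 (0 and 0 against 4 and 2), Nutf2-ps1, Mir7651 (2 and 3 against 10 and 5) and Mir5107 (0 and 2 against 10 and 5). Lower were Mir344c (6 and 8 against 1 and 1), Mir1191b (5 and 4 against 1 and 1), Mir1188 (17 and 26 against 6 and 7), Mir6911 (4 and 2 against 0 and 0), n-R5s39 (4 and 4 against 0 and 1) and Cd9. None of them passed in this test (limma adjusted p = 1.00 for each), and Snord59a, Nutf2-ps1 and Cd9 were called by voom with number as a term.

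**Figure D1:**
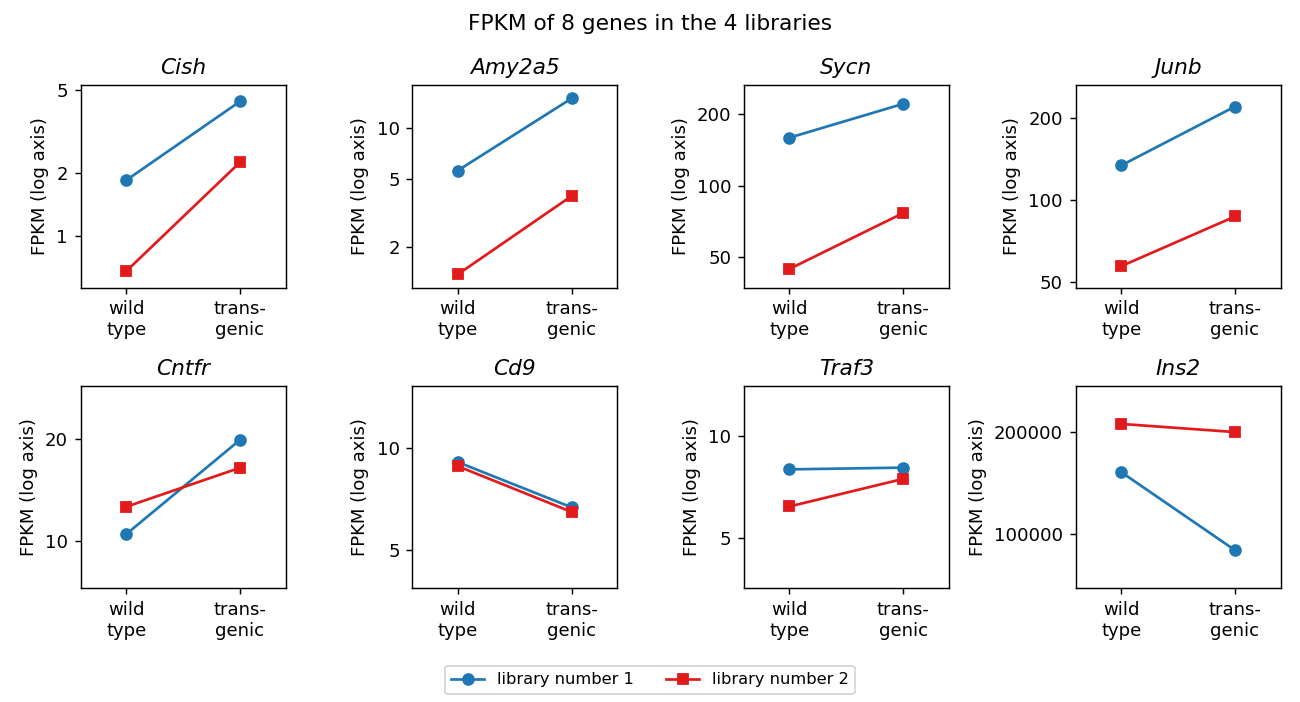
FPKM of 8 genes in each of the 4 libraries on log axes, with wild type on the left and transgenic on the right of each panel and a line joining the libraries of a number (colour and symbol). Cish, Amy2a5, Sycn, Junb and Cntfr are higher and Cd9 is lower in the transgenic library of both numbers, and Sycn and Junb differ more between numbers than between genotypes.

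Acinar genes rose as a list over all libraries (camera in limma, adjusted p = 0.0383, and 0.875 with an estimated correlation). With an estimated correlation camera had few degrees of freedom here and could call hardly any list. The call at the preset correlation ended among genes of at least 5 FPKM in 2 libraries, where camera called 0 lists higher. The syncollin gene Sycn, whose product lies in the granules that hold digestive enzymes, was at 159 and 44.7 FPKM in wild type 1 and 2 and at 221 and 76.9 in transgenic 1 and 2. The amylase gene Amy2a5 was at 5.63 and 1.38 against 15.0 and 3.99, and Bhlha15, a transcription factor gene of secretory cells, at 18.4 and 9.11 against 20.9 and 15.7. Spink1, a trypsin inhibitor gene, was at 12.7 and 6.58 against 19.9 and 8.12. Amylase genes are near-identical copies whose reads counting can split, so Amy2a5 alone is uncertain. Limma called 0 of the 32 genes over all genes tested and 0 adjusted over the list alone. With number as a term, voom called 22 higher over all genes tested, and adjusted over the list alone 27 higher and 1 lower. Acinar genes held 1.55% and 0.299% of all FPKM in wild type 1 and 2 and 2.44% and 0.497% in transgenic 1 and 2, a transgenic to wild-type ratio of 1.57 in number 1 and 1.66 in number 2. These shares depend on Ins2, and without the 3 most abundant genes (Ins2, Ins1 and Iapp) the ratios were 1.33 and 1.61. The means, 0.923% and 1.47%, differed by less than the pooled SD of 1.15 points, and an exact permutation test of 2 against 2 libraries cannot go below a 2-sided p of 0.333. The list's median was 0.50 over all libraries, but -0.55 without wild type 2 and -0.41 without transgenic 1, since the numbers are then unequally represented.

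Immediate early genes were not called as a list over all libraries (camera adjusted p = 0.117; adjusted p = 0.875 with an estimated correlation). Junb, a subunit of the AP-1 transcription factor, lay at 134 and 57.1 FPKM in wild type 1 and 2 and at 220 and 86.8 in transgenic 1 and 2. Ier2 lay at 63.8 and 23.2 against 98.0 and 34.0, and Zfp36, whose protein destabilises cytokine messenger RNAs, at 24.5 and 11.7 against 35.3 and 17.4. Ier3 lay at 11.6 and 4.43 against 14.5 and 6.82. Limma called 0 of the 16 over all genes tested and 0 adjusted over the list alone, and voom with number as a term called 12 higher and 16 higher by these counts. The list rose in camera on that voom fit (adjusted p = 1.6e-27; adjusted p = 0.895 with an estimated correlation), as acinar genes did (3.1e-40; adjusted p = 0.895 with an estimated correlation). With the GC curve removed from that fit, the medians by number were 0.33 and 0.42 for the immediate early list. Its median over all libraries was -0.64 without wild type 2 and -0.67 without transgenic 1.

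**Figure D2:**
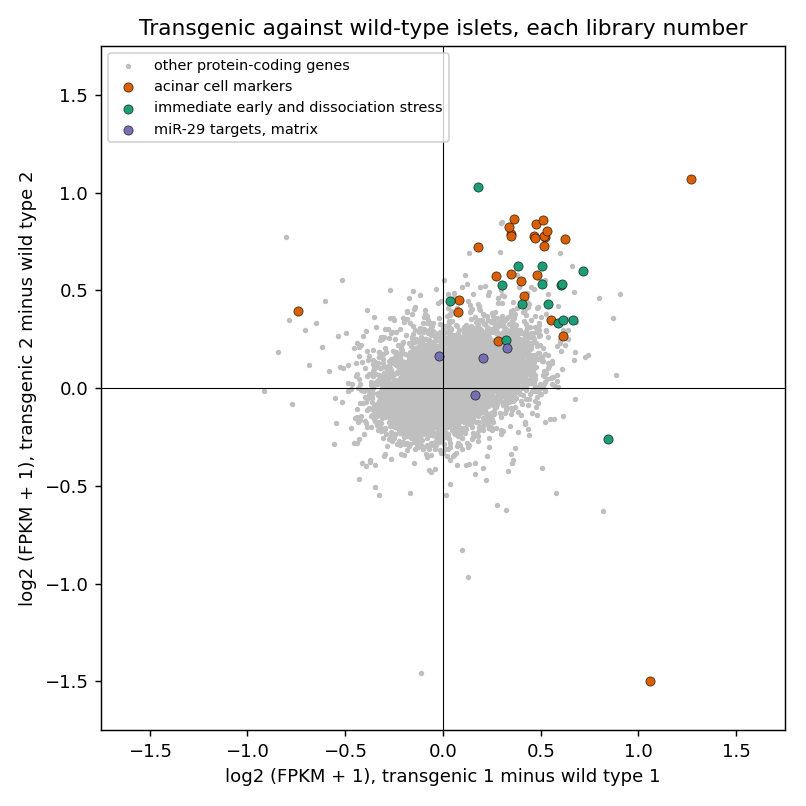
The log2 fold change of transgenic over wild type in number 2 (vertical axis) against that in number 1 (horizontal axis) for 6267 protein-coding genes of at least 5 FPKM, with the acinar, immediate early and matrix miR-29 target lists coloured. Acinar and immediate early genes lie mostly in the upper right quadrant, higher in transgenic islets of both numbers, and the correlation across all points is 0.353.

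**Figure D3:**
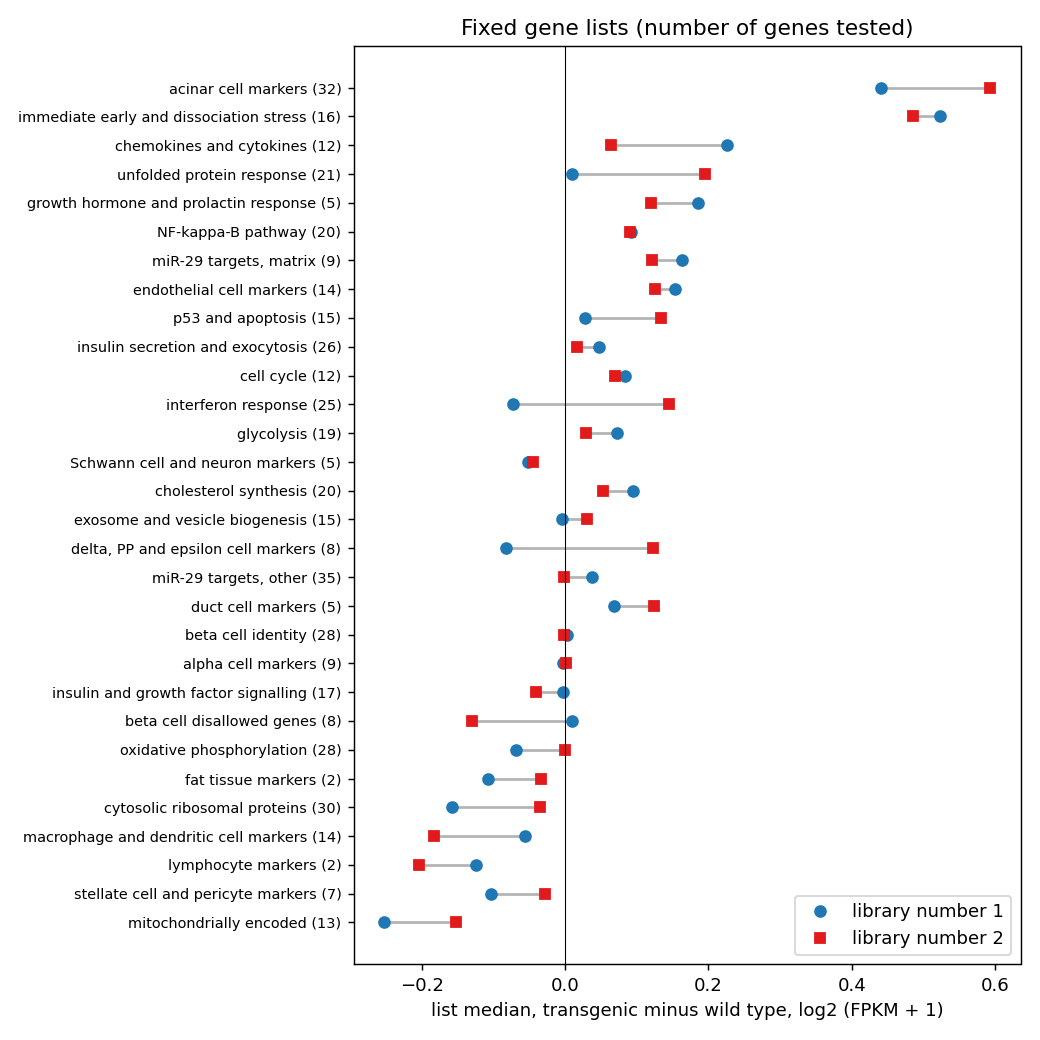
Median log2 fold change of transgenic over wild type in number 1 and in number 2 for each of the 30 gene lists, a pair of points per list. Acinar genes (0.44 and 0.59) and immediate early genes (0.52 and 0.49) stand above the other lists, and mitochondrially encoded genes (-0.25 and -0.15, plotted with the GC curve in place) are lower in both numbers.

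The 13 mitochondrially encoded genes fell as a list (camera adjusted p = 8.4e-05; adjusted p = 0.875 with an estimated correlation), 8 of them lower in both numbers. mt-Co1, a subunit of cytochrome c oxidase, lay at 7902 and 6772 FPKM in wild type 1 and 2 against 5786 and 6095 in transgenic 1 and 2, and mt-Nd6, a subunit of complex I, at 1729.8 and 1725 against 1452 and 1447. The log2 fold change of mt-Nd4l was -0.11 in number 1 and -1.46 in number 2. The list's call ended without wild type 2 and, in the test across all libraries, with no filter on low values, where camera called 0 lists lower. In that test it also ended once the curve on GC content was removed, where the list's median went from -0.25 to -0.10. In voom with number as a term the list fell (camera adjusted p = 6.2e-08; adjusted p = 0.895 with an estimated correlation), also with the GC curve removed, where its median was -0.06, with 0.00 in number 1 and -0.05 in number 2 (0.00706; adjusted p = 0.692 with an estimated correlation). The 30 cytosolic ribosomal protein genes also fell as a list (camera adjusted p = 0.0206; adjusted p = 0.875 with an estimated correlation), with medians of -0.16 and -0.03 and 16 genes lower in both numbers. Rps27a, which encodes ubiquitin fused to a ribosomal protein, had log2 fold changes of -0.56 in number 1 and -0.29 in number 2. The median, -0.09, was 0.01 without transgenic 1, and the call also ended without wild type 2 and with no filter on low values. In voom with number as a term the ribosomal list fell (camera adjusted p = 1.5e-04; adjusted p = 0.895 with an estimated correlation), also with the GC curve removed, where its median was -0.14, with -0.20 in number 1 and -0.07 in number 2 (1.4e-10; adjusted p = 0.692 with an estimated correlation). Nuclear genes of oxidative phosphorylation were not called (28 genes, medians -0.07 and 0.00, camera adjusted p = 0.516).

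Known targets of miR-29 were not lower as lists in transgenic islets. The RNA was of whole islets and the transgene is in beta cells. A fall within beta cells can therefore be hidden in genes that other islet cells express. Of 30 listed matrix targets, 9 were high enough to be compared, and they had medians of 0.16 and 0.12, with 6 higher and 0 lower in both numbers (camera adjusted p = 0.0971). In voom with number as a term and the GC curve removed the medians were 0.01 and 0.07 (camera adjusted p = 0.563). The basement membrane collagen genes Col4a1 and Col4a2 lay at 14.7 and 8.69 FPKM in wild type 1 and at 17.0 and 11.1 in transgenic 1. In wild type 2 they lay at 16.6 and 6.93 and in transgenic 2 at 18.6 and 8.15. Col3a1 had a log2 fold change of 0.11 ± 0.25. Col1a1 was below the level compared, with 82, 158, 119 and 146 reads in wild type 1 and 2 and transgenic 1 and 2. Over the 35 other targets the medians were 0.04 and 0.00, with 14 higher and 10 lower in both numbers (camera adjusted p = 0.746). Of these 35, voom with number as a term called 2 higher and 0 lower, Zfp36 (adjusted p = 1.7e-04) and Bbc3 (0.0193, and 0.792 with the GC curve removed, where its fold went from 0.46 ± 0.11 to 0.17 ± 0.11). Traf3, an adaptor that restrains NF-kappa-B signalling, lay at 7.98 and 6.19 FPKM in wild type 1 and 2 and at 8.07 and 7.48 in transgenic 1 and 2, a log2 fold change of 0.13 ± 0.16. The DNA methyltransferase genes Dnmt3a and Dnmt3b had log2 fold changes of -0.03 ± 0.14 and 0.18 ± 0.25 and the survival gene Mcl1 0.11 ± 0.22, each smaller than 1 standard error. These standard errors, like those of Col3a1 and Traf3, come from the fit without number and include the difference between numbers. They therefore do not show that these genes were unchanged. Stx1a, a membrane fusion protein that acts in insulin secretion, was higher in both numbers (0.34 and 0.38) and was not called by limma or by voom with number as a term (adjusted p = 0.0719). The lactate transporter gene Slc16a1 had 15, 9, 25 and 9 reads and Onecut2 65, 52, 34 and 33 in wild type 1 and 2 and transgenic 1 and 2. In FPKM, Onecut2 was lower in transgenic islets of both numbers, at 0.203 and 0.150 against 0.0985 and 0.117. Slc16a1 was higher in both, at 0.142 and 0.0784 against 0.219 and 0.0968. Both genes lay under the FPKM of 1 asked of genes compared, so they were not tested.

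Genes with a match to the miR-29 seed had fold changes close to those of other genes. Of 10712 protein-coding genes with a 3' UTR of at least 50 bases, 1665 had a match of 7 bases. Their median log2 fold change differed from that of the other genes of like UTR length by 0.013, which ranked at percentile 66.8 among 5760 other 7-base sequences, 95% of whose values lay between -0.049 and 0.057, and at percentile 29.2 among the 1505 of them with the same GC content. The difference was 0.027 within number 1 and 0.0017 within number 2 (percentiles 59.1 and 7.91 among sequences with the same GC content), and 0.041 and -0.019 for the library pairs across numbers. With the curve on GC content removed it was -0.0047 (percentile 17.1 among all and 5.25 among those with the same GC content). A fall of 0.02 laid on the genes with a match ranked at percentile 46.2 among all and 0.266 among sequences with the same GC content, and one of 0.05 at 11.4 and 0.

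Islet hormone genes kept near their wild-type level apart from Ins2 in number 1. Ins2 lay at 152363 FPKM in wild type 1 and 89340 in transgenic 1, and at 211742 and 200260 in wild type 2 and transgenic 2, a log2 fold change of -0.77 in number 1 and -0.08 in number 2 (-0.43 ± 0.46 over all libraries). Voom with number as a term did not call it (adjusted p = 0.132) unless the GC curve was removed (0.0340). Ins1, the other insulin gene, had fold changes of -0.16 and -0.07, glucagon (Gcg) -0.09 and -0.08, somatostatin (Sst) 0.08 and 0.14 and pancreatic polypeptide (Ppy) 0.10 and -0.05. Beta cell identity genes (28) had medians of 0.00 in both numbers (camera adjusted p = 0.990), with a list median of -0.01 and a mean of 0.02 over all libraries. Among them Mafa, a transcription factor gene of mature beta cells, lay at 102 and 141 FPKM in wild type 1 and 2 against 155 and 168 in transgenic 1 and 2, a call of voom with number as a term (adjusted p = 0.00460, fold on the reads 0.43 ± 0.09) that ended with the GC curve removed (0.695, fold 0.15 ± 0.09). Genes that beta cells keep silent (8 compared, medians 0.01 and -0.13, camera adjusted p = 0.516), alpha cell genes (9, medians 0.00 and 0.00, 0.747) and delta, PP and epsilon cell genes (8, medians -0.08 and 0.12, 0.990) were not called. The same held for insulin secretion and exocytosis (26 genes, medians 0.05 and 0.02, 0.568) and insulin and growth factor signalling (17, medians 0.00 and -0.04, 0.990).

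Markers of other islet cells moved less than acinar genes. Endothelial genes (14) had medians of 0.15 and 0.13 and were not called over all libraries (camera adjusted p = 0.117). In voom with number as a term the list rose (0.0154; adjusted p = 0.895 with an estimated correlation), also with the GC curve removed (0.0202; adjusted p = 0.692 with an estimated correlation). Plvap, a protein of endothelial fenestrae, lay at 45.4 and 35.3 FPKM in wild type 1 and 2 and at 66.0 and 46.3 in transgenic 1 and 2, called higher by voom with number as a term (adjusted p = 0.00128, fold on the reads 0.47 ± 0.09) but not with the GC curve removed (0.234, fold 0.24 ± 0.09). Macrophage and dendritic cell genes (14) had medians of -0.06 and -0.18, 8 of them lower in both numbers, and missed the threshold (camera adjusted p = 0.0507). With number as a term the list fell on log2(FPKM + 1) (camera adjusted p = 0.0282, and 0.943 with an estimated correlation). Voom with number as a term did not call it (camera adjusted p = 0.0635) unless the GC curve was removed (camera adjusted p = 5.7e-05, and 0.692 with an estimated correlation). Lyz2, a macrophage lysozyme gene, lay at 11.7 and 9.82 FPKM against 9.34 and 7.56, and Adgre1 at 1.29 and 1.42 against 0.874 and 0.911. The camera adjusted p was 0.172 for stellate cell and pericyte genes (7, medians -0.10 and -0.03), 0.922 for duct genes (5, 0.07 and 0.12) and 0.990 for Schwann cell and neuron genes (5, -0.05 and -0.04). For lymphocyte genes (2, -0.12 and -0.20) it was 0.746 and for fat tissue genes (2, -0.11 and -0.03) 0.668. By share of all FPKM, alpha cell genes held 3.10% and 2.71% in wild type 1 and 2 and 3.46% and 2.66% in transgenic 1 and 2. Endothelial genes held 0.0257% and 0.0188% against 0.0373% and 0.0227%, macrophage and dendritic cell genes 0.0530% and 0.0487% against 0.0683% and 0.0431%, and lymphocyte genes 0.00200% and 0.00182% against 0.00244% and 0.00143%. These shares depend on Ins2 too, which held 33.1% of all FPKM in wild type 1 and 23.0% in transgenic 1. A higher share in transgenic 1 is therefore not by itself a rise of these genes.

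Genes of inflammation, stress and metabolism were not called as lists over all libraries. Nfkbia, the NF-kappa-B inhibitor gene, lay at 56.6 and 51.5 FPKM in wild type 1 and 2 and at 90.9 and 58.6 in transgenic 1 and 2 (voom with number as a term, adjusted p = 0.00582), while the NF-kappa-B list had medians of 0.09 and 0.09 over 20 genes (camera adjusted p = 0.220). In voom with number as a term the NF-kappa-B list rose (camera adjusted p = 0.00128; adjusted p = 0.895 with an estimated correlation), and so did the unfolded protein response (0.0154; adjusted p = 0.895 with an estimated correlation). With the GC curve removed as well, their adjusted p were 1.2e-04 and 8.5e-04 (adjusted p = 0.692 with an estimated correlation for both). Bbc3, a pro-apoptotic gene and a listed miR-29 target, lay at 9.86 and 6.81 against 13.5 and 9.34, and the p53 and apoptosis list had medians of 0.03 and 0.13 over 15 genes (0.568). The growth hormone and prolactin list that holds Cish had medians of 0.19 and 0.12 over 5 genes (camera adjusted p = 0.384). Medians were 0.23 and 0.06 for chemokines and cytokines (12 genes, camera adjusted p = 0.668), -0.07 and 0.14 for the interferon response (25, 0.458) and 0.01 and 0.19 for the unfolded protein response (21, 0.861). They were 0.08 and 0.07 for the cell cycle (12, 0.624), 0.07 and 0.03 for glycolysis (19, 0.568), 0.09 and 0.05 for cholesterol synthesis (20, 0.990) and 0.00 and 0.03 for exosome and vesicle biogenesis (15, 0.922), the list that holds Cd9. In each of the 30 lists limma called 0 genes over all genes tested and 0 adjusted over the list alone, and the adjusted p of fry was 0.986 or higher in that fit. In voom with number as a term and the GC curve removed, fry called the cell cycle list (fry adjusted p = 0.00708, camera adjusted p = 0.220). In simulated data camera called a list of 30 genes changed 1.4-fold in 5 of 5 simulations, and shorter lists, such as the 9 matrix targets of miR-29, were not simulated. The simulated lists were random genes drawn independently, so the result does not carry over to lists whose genes shift together between numbers. The median, the mean and the direction of the camera test did not all share a sign, with medians and means near 0, for beta cell identity, insulin signalling, cholesterol synthesis, exosome and delta, PP and epsilon cell genes.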

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

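The alternatives with the GC curve, a minimum gene length or voom were chosen after seeing the data. The count of 0 genes called by limma across all libraries stayed 0 under other pseudocounts, filters, scalings, eBayes settings, leaving out any library, and voom with genotype only. The library numbers share no origin in the labels, and the correlation of the deviations of same-numbered libraries was 0.775. With the replicate block, limma on log2(FPKM + 1) still called 0 genes, 1360 of them at an unadjusted p under 0.05, and 4 with the GC curve removed (3 higher and 1 lower). Voom with the replicate block called 238 genes (204 higher and 34 lower), 111 with the GC curve removed (81 and 30), 107 with quantile normalization (89 and 18) and 102 with the curve removed among genes of at least 200 bases (77 and 25). Of the gene lists, 3 were called by camera across all libraries, acinar genes higher and mitochondrially encoded and ribosomal protein genes lower. With no filter on low values 1 was called, higher, and the calls of both falling lists ended. At 5 FPKM or more in 2 libraries 0 were called higher and 4 lower, so the call of acinar genes ended. With the replicate block on log2(FPKM + 1) 7 were called, 8 with the GC curve removed and 7 among genes of at least 200 bases. With voom and the replicate block 7 were called, 9 with the GC curve removed, 6 with quantile normalization and 9 with the curve removed among genes of at least 200 bases. With an estimated correlation 0 were called, 0 with voom and the replicate block, and 0 with the GC curve removed as well. The p-values of that test rest on the few residual degrees of freedom of 4 libraries, so a list could hardly pass whatever its shift. Fry called 0 without number. In voom with the replicate block and the GC curve removed it called the cell cycle list (fry adjusted p = 0.00708). Leaving out a library gave 3 to 9 lists, and list medians with a call changed sign only there. They ran from -0.55 (without wild type 2; -0.41 without transgenic 1) to 1.58 for acinar genes, from -0.67 (without transgenic 1; -0.64 without wild type 2) to 1.55 for immediate early genes, and from -0.47 (without wild type 2; -0.26 without transgenic 1) to 0.62 for the unfolded protein response. For chemokines and cytokines they ran from -0.28 to 0.52, with -0.25 called without transgenic 1, and for ribosomal protein genes from -0.25 to 0.0058 (without transgenic 1). Leaving out 1 library leaves the numbers unequal between genotypes by construction, and the lone library of a group is then assumed to vary like the other group. For the other changes the cause was not tested. In the remaining settings of the fit without number, 317 list values kept their side of the threshold, 5 came past it and 4 no longer passed it. Of single genes, 1631 values kept their side there, and 3 and 112 came past it with the block on log2(FPKM + 1) and in voom. The seed difference (0.013) moved by less than the spread of the 4 library pairs (0.0266) under each alternative run, to 0.0089 with matches of 8 bases, 0.029 with 6 bases included, 0.020 at 5 FPKM or more and -0.0047 with the GC curve removed. That spread includes the pairs across numbers and exceeds the difference itself, so this does not show that its sign is stable. In library composition, the acinar share differed by 0.687 points without the 3 most abundant genes and by -0.426 to 1.51 points when leaving out a library, each less than 1 SD (1.15 points) from the 0.544 over all libraries. That SD is set mostly by the split between numbers, so lying within it does not show a stable difference, and -0.426 has the opposite sign. Tests that model counts were not run, and at 5 FPKM some lists had too few genes for a value.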

Other observations

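Chosen only after the result was seen were the comparison between library numbers, the tests of acinar tissue in number 1, of acinar tissue carrying the immediate early genes and of a single RNA, and the swapped grouping. Apart from genotype, the libraries numbered 1 held more stress and exocrine transcripts than those numbered 2. With voom on the recovered reads, 2746 genes were higher and 2799 lower in number 2, 279 and 519 of them over 2-fold. All 32 acinar genes (median log2 difference of number 2 from number 1 -2.10) and all 16 immediate early genes (-2.18) fell, as did 9 chemokine and cytokine genes (list median -1.41) and 19 of 21 genes of the unfolded protein response (-0.99). The stress factor Atf3 went from 107 to 17.0 FPKM in wild type and from 121 to 35.7 in transgenic islets. Of the endocrine genes, 4 of 8 delta, PP and epsilon cell genes (list median 0.29), 5 of 9 alpha cell genes (0.24) and 13 of 28 beta cell identity genes (0.14) rose in number 2, while 1 alpha cell and 2 beta cell identity genes fell. Glucagon (Gcg, -0.04, voom adjusted p = 0.792) and Ins1 (0.11, 0.517) were not called, and the lists were not tested as lists between numbers. Pancreatic polypeptide (Ppy) went from 3737 to 9089 FPKM in wild type and from 4000 to 8764 in transgenic islets, and the glucose transporter gene Slc2a2 from 57.3 to 146 and from 61.3 to 122.1. Genotype and number were not tested for interaction.

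Of 8 genes listed as responding to growth hormone and prolactin, 5 were compared and 3 were higher in both numbers, Cish by the most. Socs2 had log2 fold changes of 0.19 and 0.32 (voom with number as a term, adjusted p = 0.0804, and 0.0218 with the GC curve removed). Ivd had 0.21 and 0.04 and Ehhadh -0.35 and -0.13. Voom with number as a term called 1 higher over all genes tested, and 2 higher and 1 lower adjusted over the list alone, and it did not call the list (camera adjusted p = 0.0516). Only with the GC curve removed as well were 2 called higher over all genes tested and did the list rise (camera adjusted p = 6.7e-06; adjusted p = 0.692 with an estimated correlation).

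The difference between numbers was set against 3 technical sources. GC content accounted for an R squared of 0.0127 of it and gene length for 0.0216, which argues against both as its cause. More acinar tissue in number 1 would lower its other transcripts alike, but 209 of 6267 protein-coding genes of at least 5 FPKM were over 1.5-fold higher in number 2 of both genotypes and 349 lower, which goes beyond acinar genes. A difference in how the islets were handled before freezing may remain, and it was not tested, as the labels give no date or batch. No biological explanation was tested, since the labels give none for the numbers.

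Acinar and immediate early genes were higher in transgenic islets of both numbers. At least 0.675 of each list's median was left with the curve on GC content removed, which argues against GC content as the whole cause, although the genotype fold followed GC content with an R squared of 0.187 in number 1 and 0.0704 in number 2. More acinar tissue in the transgenic preparations would raise acinar genes alike: the SD of their folds was 0.205 in number 1 and 0.476 in number 2, and 0.140 and 0.185 over 22 genes without the amylase copies, so this stays open. Acinar tissue carrying the immediate early genes stays open too: the medians of both lists differed by at most 0.107 within a number, but this likeness is what raised the question and so does not test it. An effect of the transgene on these genes also stays open and was not tested, because genotype and islet preparation coincide in these 4 libraries.

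The folds of both numbers differed by 4.57 times the median that counting error gives. A single RNA behind both libraries of a genotype is argued against, since acinar and immediate early medians lay at least 1.91 apart on the log2 scale between the numbers of each genotype. Separate animals and a pool of islets taken up separately cannot be told apart here, since the labels name no source per library. Between libraries, this multiple was 11.5 for wild type 1 and transgenic 1, 4.86 for wild type 2 and transgenic 2, 25.6 for the wild-type pair and 27.5 for the transgenic pair, over 9030 genes with at least 200 reads in each. With the library number as a term the genotype grouping called 238 genes, and swapping genotypes in 1 number called 8. The 2 such groupings are too few for a share under 0.05. Each fit also takes the difference of the other grouping as its residual, so the 8 calls are no independent reference.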
